A study of Solanum lycopersicum with 36 samples.

How the data were processed

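The series holds 36 libraries of tomato leaf RNA, 18 of mRNA and 18 of GMUCT (genome-wide mapping of uncapped and cleaved transcripts), with 3 replicates at each of 6 times. Per the labels' protocols, plants were 4 weeks old and grew at 25 °C in 12 h light and 12 h dark. mRNA libraries were made from polyadenylated RNA and read as pairs of 150 nt, and GMUCT libraries were made from total RNA and read from a single end over 50 nt. Groups were taken from the sample labels, and every library was assigned.

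The values deposited by the authors were raw read counts per gene, not normalised, in a table per library with 34075 gene identifiers and 5 counters of reads outside genes. Per the submitters' processing notes, cutadapt, STAR 2.4.2a and HTSeq were used. Their settings, the genome build, the annotation and the handling of strand are not given in the sources used here. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart. The counters were left out of library sizes and tests. Reads counted in genes made up between 88 and 90.2% of the mRNA counts and between 54.4 and 85.3% of the GMUCT counts. Reads placed at several positions took 2.11 to 3.52% in mRNA and 8.6 to 40.2% in GMUCT, and were not counted in genes. Which features they came from is not given and was not tested. A GMUCT read marks a 5' end, so its count does not measure the length or the rate of decay of a transcript, and a ratio of GMUCT to mRNA is a relative measure within each assay's own scaling.

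Per library, between 20055 and 22614 identifiers had counts in mRNA and between 22373 and 23132 in GMUCT, and 7170 identifiers had none in any library. Of the identifiers, 11600 carry the prefix gene: and are printed as the files give them. None (0) of the 34075 identifiers was found in the reference gene table of 41476 genes, so names, functions, positions and lengths were not used. For the same reason the tests of 30 gene lists that had been fixed before the data were examined could not be run.

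Counts were analysed with edgeR 4.0.16 in R 4.3.3. Each assay was fitted alone, with 18 libraries in 6 group means, after the filter of filterByExpr and scaling by trimmed mean of M values (TMM). Quasi-likelihood F-tests (glmQLFit, glmQLFTest) asked whether a gene differed among the 6 times (5 degrees of freedom), whether the group means carried a cosine and sine of 24 h (2 degrees of freedom), and whether 2 times differed. P-values were adjusted by the method of Benjamini and Hochberg within each test, with a threshold of 0.05. For the 24 h test the groups were placed at 0, 4, 8, 12, 16 and 20 h, the label's hour being read as time since the start of that phase. One day with 6 times in a light and dark regime cannot separate a circadian rhythm from a direct response to light. The ratio of GMUCT to mRNA was tested as the interaction of assay and time in a single fit of all 36 libraries over genes that passed the filter in both assays. The 5 planned contrasts were Light 4 h and Light 8 h against Light 0 h, Dark 4 h and Dark 8 h against Dark 0 h, and Dark 0 h against Light 0 h. Dark 0 h against Light 8 h and the 3 remaining steps were added after the data had been seen.

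CPM values use TMM-scaled library sizes within an assay, and log2 CPM values a prior count of 2. The SE of a log2 change is an approximation, the absolute change divided by the square root of its F statistic. The range of a gene is the difference between its highest and lowest group mean in log2 CPM. The matched comparison of GMUCT to mRNA levels used a pseudocount of 0.5, 20 bins of mRNA CPM and 10000 random sets. Genes to be named were chosen by a rule fixed before the data were examined: the largest changes in each direction among genes past the threshold, with a mean of at least 10 CPM (in both assays for the ratio) and no overlap between the replicates of the 2 groups. The rule also asked for a known name and for 5 genes in each direction. As no names could be matched, that condition was dropped and at most 2 genes in each direction were taken per comparison. Genes whose lower group had no reads, or about 1 read, were left out of the text.

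The tests were tried on simulated counts with known changes before use. In the comparison of Dark 4 h with Dark 0 h, 47 of 100 genes seeded with a log2 change of 1 and 92 of 100 with a change of 2 were recovered in mRNA, 47 and 89 in GMUCT, and 20 and 78 in the ratio, over 19369, 20433 and 18793 simulated genes. The 24 h test recovered 194, 187 and 177 of 200 genes seeded with a log2 amplitude of 1. Changes of 2-fold were thus often missed in the simulation, in the ratio most of all, and smaller changes were not simulated. Each simulation changed 400 genes, far fewer than passed in the data. All of them had a mean above 1 CPM, so recovery of weaker genes was not simulated. The adjusted threshold depends on how many genes change, so the share missed in the data can differ. Replicates of a group correlated at r of 0.95 or more in log2 CPM, and every pair differed by more than sampling noise (chi-square per degree of freedom of at least 6.29), so none was treated as a duplicate.

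Alternatives were scaling by relative log expression and by upper quartile, no filter and a stricter filter on low counts (at least 50 counts in 3 libraries), an adjusted p of 0.01, a 2-fold minimum, the replicate number as a block, a fit of only the 2 groups compared, DESeq2 1.42.0, limma 3.58.1 (voom) for the ratio, and leaving out each library. Fits without Dark 0 h were added later.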

Results

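Leaves of tomato (Solanum lycopersicum, cultivar Heinz 1706) were sampled at 6 times of a day of 12 h light and 12 h dark. The time groups were 0, 4 and 8 h into the light (Light 0 h, Light 4 h, Light 8 h) and 0, 4 and 8 h into the dark (Dark 0 h, Dark 4 h, Dark 8 h). Each group had 3 libraries of polyadenylated RNA, called mRNA here, and 3 libraries of GMUCT, a method that sequences uncapped and cleaved transcripts from their 5' ends and so reads RNA that has entered decay or been cut. The design asks which transcripts change over the day, and whether uncapped transcripts follow the abundance of their mRNA. Gene counts summed to between 6632784 and 27126312 per mRNA library (median 15587175) and to between 15739253 and 20581411 per GMUCT library (median 18765648). The shallowest library was replicate 1 of mRNA at Dark 4 h. The labels do not say that replicates came from separate plants, so p-values measure the spread between these samples, which may be technical. The files give each gene as an identifier and no table used here pairs these with names, so genes are given by identifier and gene groups by when they changed.

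Most of the leaf's transcripts changed in abundance over the day. Of 19711 genes tested in mRNA, 13983 (70.9%) differed among the 6 times at adjusted p under 0.05 (edgeR quasi-likelihood test). In 13441 (68.2%) the group means carried a cosine and sine of 24 h at that threshold, called a 24 h rhythm here. The period was fixed and not estimated, and 1 day shows no repeat of a cycle. A single difference between day and night can pass this test too. Of the genes with the rhythm, 10293 also spanned at least 2-fold (log2 range of 1) between their lowest and highest time. The most frequent times of highest mRNA were Light 8 h, with 23.7% of these genes, and Light 4 h, with 21.9%. Light 0 h held 18% of the peaks, Dark 0 h 16.1%, Dark 4 h 10.1% and Dark 8 h 10.2%. The gene with the widest range, gene:Solyc02g070940.1, spanned 9.88 on the log2 scale (adjusted p = 1.93e-09 for the rhythm). It had 1840 ± 68.5 CPM (read counts scaled to library size; SD, n = 3) at Light 4 h, 622 ± 146 at Light 8 h, 41 ± 16.5 at Dark 0 h and 3.64 ± 3.04 at Dark 8 h. gene:Solyc02g070970.1, with an identifier close by, followed with a range of 9.7 and peaked at the same time, with 583 ± 44.6 CPM at Light 4 h against 0.831 ± 0.475 at Light 0 h. Whether these genes share reads with near-identical copies could not be checked, so the values of such neighbours are uncertain.

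Uncapped transcripts were also rhythmic, with another distribution of peaks. Of 20696 genes tested in GMUCT, 12087 (58.4%) differed among the 6 times and 12973 (62.7%) carried the 24 h rhythm, 7620 of them with a range of at least 2-fold. Dark 0 h was the most frequent time of highest GMUCT signal, with 27% of these 7620 genes, against 12.7% at Light 8 h. Light 0 h held 19.4%, Light 4 h 18.7%, Dark 4 h 11.5% and Dark 8 h 10.7%. In both assays a peak is the highest group mean, which was not tested against the next highest. Between Light 8 h and Dark 0 h, 8.67% of the genes tested in GMUCT passed the threshold. For many genes the higher of these 2 times is therefore not settled. The widest range belonged to gene:Solyc03g005760.1, which spanned 13.79 on the log2 scale (adjusted p = 1.72e-12). Its GMUCT signal was 4340 ± 520 CPM at Light 4 h, 7940 ± 248 at Light 8 h and 6590 ± 448 at Dark 0 h, and 6.45 ± 3.55 at Dark 4 h (SD, n = 3). Its neighbour by identifier, gene:Solyc03g005770.3, had a range of 12.23, from 0.36 ± 0.129 CPM at Dark 8 h to 2210 ± 370 at Light 8 h.

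**Figure D1:**
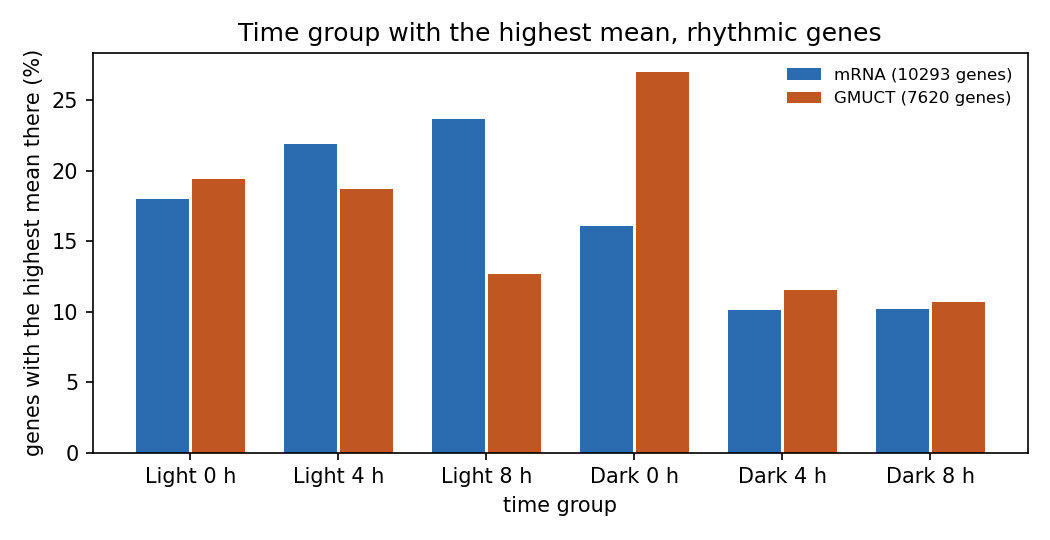
Share of rhythmic genes (y axis, %) that had their highest mean at each time group (x axis), for mRNA (blue, 10293 genes) and GMUCT (orange, 7620 genes). Genes passed the 24 h rhythm test and spanned at least 2-fold. Dark 0 h held 16.1% of the mRNA peaks and 27% of the GMUCT peaks. The highest mean of a gene was not tested against its next highest.

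From Light 0 h to Light 4 h and to Light 8 h, mRNA and uncapped transcripts of the same genes mostly rose and fell together. At Light 4 h, 4409 genes were higher and 4895 lower in mRNA than at Light 0 h, and 3060 were higher and 3271 lower in GMUCT. Among the 19161 genes tested in both assays, 2089 were higher in both and 2389 lower in both, against 673 and 806 for independent lists of the same sizes. Only 20 were higher in mRNA and lower in GMUCT, and 35 the opposite. Across genes the log2 changes correlated with r = 0.68 (Spearman's rho = 0.66), and with r = 0.8 over the 9880 genes of at least 10 CPM in both assays. At Light 8 h, 5122 genes were higher and 5079 lower in mRNA, and 3704 higher and 4026 lower in GMUCT, with r = 0.69 across genes. From Light 4 h to Light 8 h, a step added after the data had been seen, r was lower, at 0.44 (0.56 at the minimum of 10 CPM), with 602 genes higher and 590 lower in both against 133 and 95, and 36 and 5 opposite. Genes are not independent replicates, so these correlations describe the libraries and carry no p-value.

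gene:Solyc02g070970.1 rose in mRNA by 9.55 ± 0.78 (log2, SE) from Light 0 h to Light 4 h (adjusted p = 2.57e-08). Its GMUCT signal rose from 0.465 ± 0.34 to 233 ± 149 CPM (8.94 ± 0.71, adjusted p = 3.75e-07). gene:Solyc02g071000.1 rose from 0.778 ± 0.128 to 328 ± 19.3 CPM in mRNA (log2 change 8.75 ± 0.71; adjusted p = 2.39e-08). In the other direction, gene:Solyc03g083730.1 fell from 541 ± 131 to 9.76 ± 0.77 CPM in mRNA, a log2 change of -5.79 ± 0.32 (SE), and from 16.9 ± 3.69 to 1.25 ± 0.33 CPM in GMUCT. At Light 8 h, Solyc08g007130 had fallen from 1370 ± 198 to 21.7 ± 5.07 CPM in mRNA and from 724 ± 105 to 1.56 ± 0.348 CPM in GMUCT (log2 change -8.85 ± 0.5, SE; adjusted p = 2.93e-09). CPM values are means ± SD of 3 libraries.

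The first 4 h of the dark moved the assays with little correlation between them, and later steps of the night with more. From Dark 0 h to Dark 4 h, 2475 genes rose and 2189 fell in mRNA, and 2645 rose and 2694 fell in GMUCT. Of the genes tested in both assays, 451 rose in both and 403 fell in both, against 329 and 291 for independent lists, while 346 and 268 went in opposite directions, against 333 and 288. Across genes the log2 changes correlated with r = 0.04 (-0.021 without replicate 3, so the sign was not settled), and with r = 0.17 over the genes of at least 10 CPM. By Dark 8 h the correlation was 0.31 (0.48 at that minimum), and 1262 genes had risen and 924 had fallen in both assays, against 551 and 506 for independent lists, with 168 and 221 in opposite directions against 563 and 495. The steps without Dark 0 h, added after the data had been seen, also went together. From Dark 4 h to Dark 8 h r was 0.26 (0.47 at that minimum), with 177 genes higher and 227 lower in both against 27 and 39, and 6 in each opposite direction. From Dark 8 h to Light 0 h r was 0.39 (0.53), with 317 higher and 111 lower in both against 29 and 11, and 0 and 1 opposite. In total, 2640 genes were higher and 2399 lower in mRNA at Dark 8 h than at Dark 0 h, and 4171 higher and 4316 lower in GMUCT. Replicate 2 of GMUCT at Dark 4 h weighed on one of these counts: without it, 1660 genes fell in GMUCT from Dark 0 h to Dark 4 h. A fit of only the 2 groups compared called fewer genes: 1400 higher in mRNA and 1401 higher and 1440 lower in GMUCT at Dark 4 h, and 1405 higher in mRNA and 2759 higher in GMUCT at Dark 8 h.

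Of the genes named for these contrasts, some changed in 1 assay past the threshold and some in both. gene:Solyc08g080670.1 had 71.4 ± 26.8 CPM in mRNA at Dark 0 h and 0.406 ± 0.251 at Dark 4 h (log2 change -7.7 ± 0.44, SE; adjusted p = 3.58e-09), while its GMUCT signal was 0.21 ± 0.148 CPM at Dark 0 h and 0.614 ± 0.439 at Dark 4 h (adjusted p = 0.211). These GMUCT values lie near the floor, so a change in that assay could hardly be seen. Solyc12g099790 rose in mRNA from 4.19 ± 0.993 to 151 ± 64.3 CPM (5.18 ± 0.46, adjusted p = 3.86e-07), with GMUCT values of 43.6 ± 36.1 and 79.5 ± 57.3 CPM (adjusted p = 0.328; adjusted p = 0.000287 for the change in ratio). In GMUCT, gene:Solyc02g070940.1 fell from 1640 ± 352 to 0.887 ± 0.575 CPM (-10.81 ± 0.53, adjusted p = 1.11e-09), and in mRNA by 3.19 on the log2 scale, from 41 ± 16.5 to 4.08 ± 2.99 CPM. Solyc03g115920 rose in GMUCT from 10.2 ± 2.15 to 85.2 ± 29.7 CPM (3.06 ± 0.33, adjusted p = 1.23e-05) with mRNA at 58.7 ± 3.17 and 52 ± 8.44 CPM (adjusted p = 0.492; adjusted p = 3.54e-07 for the change in ratio). By Dark 8 h, gene:Solyc09g009420.1 had fallen from 243 ± 56.8 to 1.86 ± 0.369 CPM in mRNA and from 32.9 ± 12.1 to 0.58 ± 0.491 CPM in GMUCT, and Solyc02g036370 had risen from 52.2 ± 2.07 to 513 ± 77.9 CPM in mRNA and from 12 ± 0.51 to 323 ± 51.3 CPM in GMUCT. Groups are given as mean ± SD of 3 libraries and log2 changes with their SE.

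The start of the dark differed strongly from the start of the light in both assays. At Dark 0 h, 3317 genes were higher and 3948 lower in mRNA than at Light 0 h, and 4835 were higher and 4779 lower in GMUCT. The changes correlated with r = 0.36 across genes (0.49 over genes of at least 10 CPM). Solyc05g014280 was lower at Dark 0 h in both assays, with 5.79 ± 2.02 against 400 ± 87 CPM in mRNA and 0.19 ± 0.145 against 22.1 ± 10.6 CPM in GMUCT (SD, n = 3). Solyc10g005080 was lower as well, with a log2 change of -8.63 ± 0.38 (SE; adjusted p = 1.49e-10) in GMUCT, from 938 ± 115 to 2.38 ± 1.15 CPM, and 19.1 ± 4.72 against 243 ± 9.92 CPM in mRNA.

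The step from Light 8 h to Dark 0 h, the last 4 h of the light by the assumed hours, separated the assays most. This comparison was added after the profiles of the 6 groups had been seen. In mRNA 4138 genes were higher and 4467 lower at Dark 0 h, close to the number that changed in the first 4 h of light. In GMUCT 966 were higher and 829 lower. The 4428 genes lower in mRNA that were tested in both assays had a median log2 change of -1.35 in mRNA and of 0.07 in GMUCT, with quartiles of -0.28 and 0.39. For the 3996 genes higher in mRNA the medians were 1.00 in mRNA and -0.06 in GMUCT. Across genes the 2 changes correlated with r = 0.03 (-0.013 to 0.099 with a replicate number left out, so the sign was not settled). Spearman's rho was -0.07. Over the 9880 genes of at least 10 CPM in both assays r was 0 and rho -0.1. Solyc01g008510 fell in mRNA from 43.2 ± 11.7 to 0.152 ± 0.181 CPM (log2 change -8.11 ± 0.6, SE; adjusted p = 9.04e-09), with GMUCT at 17.2 ± 7.66 and 5.62 ± 4.35 CPM (adjusted p = 0.107). gene:Solyc05g052670.1 rose from 1.12 ± 0.646 to 270 ± 31.4 CPM in mRNA and from 0.203 ± 0.0874 to 5.82 ± 5.46 CPM in GMUCT. Solyc03g115770 rose in GMUCT from 1.42 ± 0.554 to 105 ± 4.64 CPM (6.19 ± 0.33, adjusted p = 2.19e-08) and in mRNA from 59 ± 24.3 to 184 ± 32.9 CPM. The GMUCT counts depended on single libraries. Higher genes numbered 432 without replicate 3 of Dark 0 h and 519, 435 and 515 without replicates 1, 2 and 3 of Light 8 h, and lower genes numbered 1265 and 359 without replicates 2 and 3 of Dark 0 h and 531, 422 and 461 without those of Light 8 h. DESeq2 called 1508 genes higher in GMUCT.

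**Figure D2:**
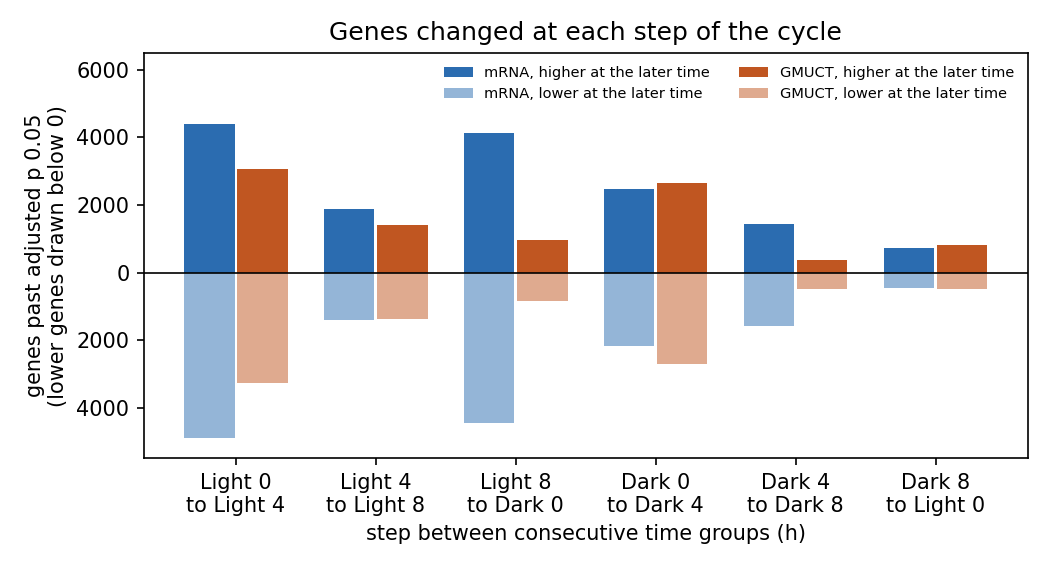
Number of genes (y axis) that passed adjusted p under 0.05 at each step between consecutive time groups (x axis, hours into light or dark), with genes higher at the later time above 0 and lower genes below 0, for mRNA (blue) and GMUCT (orange). From Light 8 h to Dark 0 h the counts were 4138 and 4467 in mRNA and 966 and 829 in GMUCT.

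**Figure D3:**
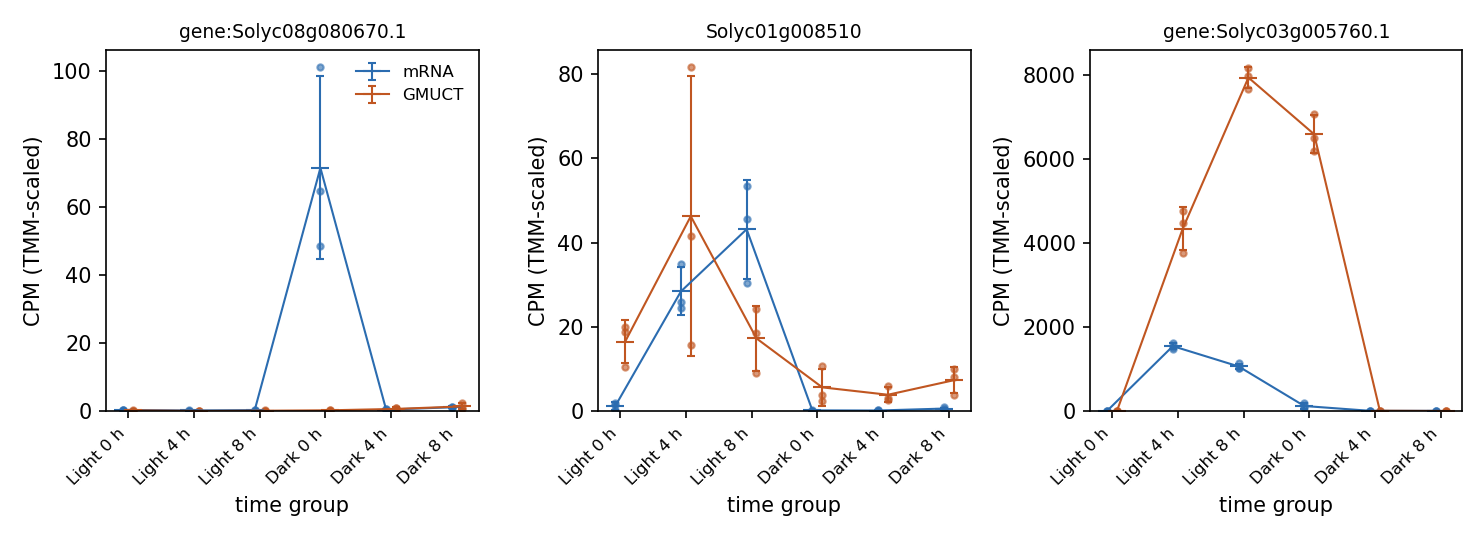
CPM (y axis) at the 6 time groups (x axis) for 3 genes in mRNA (blue) and GMUCT (orange). Points are the 3 libraries of a group, and horizontal marks with bars give their mean and SD. gene:Solyc08g080670.1 had mRNA of 71.4 ± 26.8 CPM at Dark 0 h and of at most 1.09 ± 0.248 CPM at the other times, Solyc01g008510 fell to 0.152 ± 0.181 CPM of mRNA at Dark 0 h, and gene:Solyc03g005760.1 kept 6590 ± 448 CPM of GMUCT signal at Dark 0 h, when its mRNA was at 119 ± 60.3 CPM.

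When each time group was described by the deviation of every gene from its own mean over the day, 5 of the 6 mRNA groups correlated best with the GMUCT group of the same time. Over 9880 genes the own-time r was 0.77 at Light 0 h, 0.7 at Light 4 h, 0.67 at Light 8 h, 0.72 at Dark 4 h and 0.75 at Dark 8 h. At Dark 0 h it was -0.05. mRNA at Dark 0 h correlated best with GMUCT at Dark 4 h (r = 0.29), and GMUCT at Dark 0 h with mRNA at Light 8 h (r = 0.63). The mRNA libraries of Dark 0 h did not agree on their best match, which was Dark 4 h for replicates 1 and 2 (r = 0.25 and 0.32) and Dark 8 h for replicate 3 (r = 0.31), while all 3 GMUCT libraries of Dark 0 h matched Light 8 h best. Among the libraries of the other times, 15 of 15 in mRNA and 15 of 15 in GMUCT correlated best with their own time in the other assay.

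**Figure D4:**
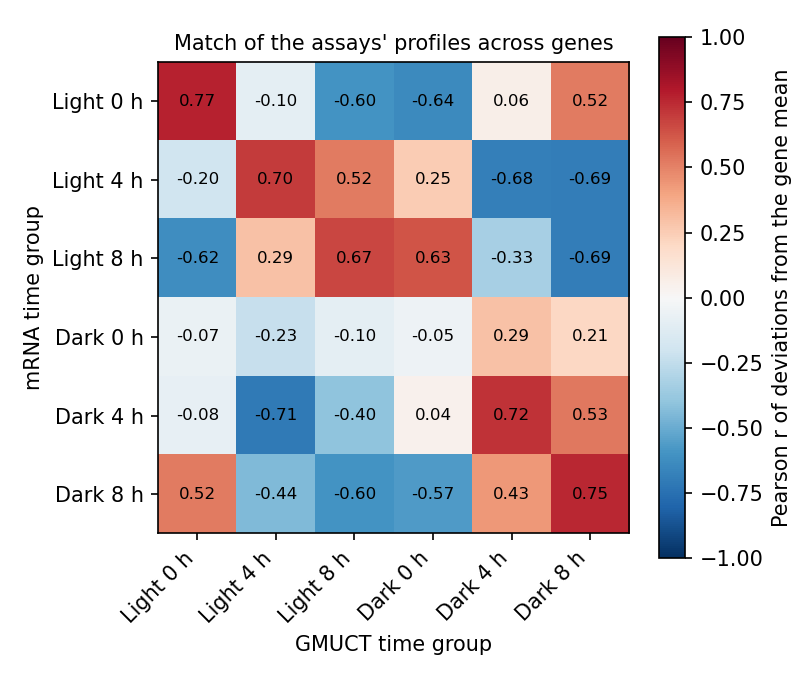
Pearson r across 9880 genes (colour and printed value) between each mRNA time group (vertical axis) and each GMUCT time group (horizontal axis), computed on the deviation of a gene's mean log2 CPM from its mean over the 6 groups. The values on the diagonal lie between 0.67 and 0.77 except at Dark 0 h, where r is -0.05.

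The ratio of GMUCT to mRNA changed with time in 10286 of the 19161 genes tested in both assays (53.7%, edgeR quasi-likelihood test of the interaction of assay and time), and in 8601 (44.9%) it followed a 24 h rhythm. Among the planned contrasts and Light 8 h to Dark 0 h, those with Dark 0 h held more genes than Light 4 h and Light 8 h against Light 0 h, except that a fit of only the 2 groups compared put Dark 8 h against Dark 0 h (1168 higher and 1181 lower) below both of these. From Light 8 h to Dark 0 h the ratio rose in 3928 genes and fell in 3681, and between Light 0 h and Dark 0 h it was higher at Dark 0 h in 3431 and lower in 2750. From Dark 0 h it rose in 2288 genes and fell in 2680 by Dark 4 h, and rose in 2134 and fell in 2590 by Dark 8 h. A fit of only the 2 groups gave 1470 and 1714 for Dark 4 h. Solyc09g089930 gained ratio by Dark 4 h (log2 change 6.19 ± 0.5, SE; adjusted p = 9.61e-10), with mRNA going from 39.5 ± 13.1 to 1.63 ± 0.634 CPM and GMUCT from 19.5 ± 11.9 to 54 ± 11.3 CPM. gene:Solyc02g070940.1 lost ratio over the same hours (-7.6 ± 0.89, adjusted p = 5.39e-07). Solyc08g080650 lost ratio from Light 8 h to Dark 0 h (-7.86 ± 0.7, adjusted p = 2.14e-09), with mRNA going from 1.36 ± 0.285 to 44.8 ± 3.13 CPM and GMUCT from 37.9 ± 20.6 to 5.45 ± 0.75 CPM. When Dark 0 h was left out of both assays, 6537 genes still passed the test of any change in the ratio.

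For Light 4 h against Light 0 h, the number of genes with a changed ratio depended on the fit and on single libraries. For Light 8 h against Light 0 h, the number with a higher ratio depended on a single library. The ratio was higher at Light 4 h than at Light 0 h in 1448 genes and lower in 945, a split that depended on scaling, since factors by relative log expression gave 1176 higher and 1196 lower. At Light 8 h the counts were 1556 and 1274. A fit of only the 2 groups compared gave 1406 higher and 1519 lower at Light 4 h and 1428 and 1491 at Light 8 h. At Light 4 h, DESeq2 called 1484 genes lower, and a fit with no filter on low counts 951 higher. Solyc02g093720 lost ratio by Light 4 h (log2 change -5.48 ± 0.5, SE; adjusted p = 1.2e-07), as its mRNA rose from 3.58 ± 1.16 to 177 ± 8.04 CPM with GMUCT at 191 ± 25.2 and 200 ± 16.9 CPM. Solyc12g044330 gained ratio (5.02 ± 0.74, adjusted p = 6.3e-05), as its mRNA fell from 74.9 ± 13.8 to 3.28 ± 0.851 CPM with GMUCT at 13.7 ± 6.31 and 18.8 ± 3.32 CPM. Without replicate 2 of mRNA at Light 0 h, the genes of higher ratio numbered 724 at Light 4 h and 846 at Light 8 h. At Light 4 h they numbered 955 without replicate 1 of mRNA at Light 4 h, and the genes of lower ratio 610 without replicate 1 of GMUCT at Light 4 h.

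By the median over genes, uncapped transcripts peaked slightly later than mRNA, but not from every time. For the 9785 genes with a 24 h rhythm in both assays, the fitted peak of GMUCT followed that of mRNA by a circular median of 1.2 h, with a range of 0.9 to 1.45 h when each replicate number was left out. The peaks lay within 2 h of each other in 50.5% of these genes, GMUCT was later by more than 2 h in 37% and earlier in 12.6%. Of the 1474 genes with mRNA highest at Light 8 h and a range of at least 2-fold in both assays, 58.3% had their highest GMUCT signal at Dark 0 h and 26.6% at Light 8 h. GMUCT passed the threshold between these 2 times in 8.67% of all genes tested, so their order is not settled for many genes. By contrast, 63.2% of the 971 genes with mRNA highest at Light 0 h and 57.5% of the 1364 highest at Light 4 h had their highest GMUCT signal at the same time. Of the 508 genes with mRNA highest at Dark 4 h, 31.1% had their highest GMUCT signal earlier, at Dark 0 h, 25.8% at the same time and 23.2% at Dark 8 h. The 717 genes with mRNA highest at Dark 0 h were spread, with 26.5% at Dark 4 h, 20.6% at the same time, 16.7% at Light 0 h and 14.2% at Light 8 h. Fitted to the 5 times other than Dark 0 h, the median delay was 0.35 h.

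Genes with a rhythm of at least 2-fold had a slightly lower level of uncapped transcript per mRNA than other genes, a difference that was near 0 with no minimum on the range. The median log2 ratio of GMUCT to mRNA CPM was 0.28 for the 10035 genes with a rhythmic mRNA of at least 2-fold range and 0.35 for random sets of the 9125 other genes matched on mean mRNA CPM, whose medians ran from 0.30 to 0.40. The other genes include rhythmic ones of smaller range. The difference was -0.06, and by replicate number it was -0.07 ± 0.046 (SD, n = 3). With no minimum on the range of the rhythm, the difference was -0.004. The ratio of a gene also depends on the length of its transcript, for which no values were used here.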

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

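The tests of exchanged time labels, of a delay, of another harvest time and of regrouped libraries were chosen only after the results they concern had been seen, and the remaining tests before.

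The ratio of GMUCT to mRNA differed between Light 8 h and Dark 0 h by a test of the difference between the assays, higher in 3928 genes and lower in 3681, as mRNA changed in 8605 genes and GMUCT in 1795. An exchange of labels with another mRNA time needs a partner out of place, and 0 of the other 5 mRNA groups correlated best with another GMUCT time. That count was already part of the pattern as first seen, so it is no separate test. A single aberrant mRNA library needs the match to return without it, yet the highest own-time r of Dark 0 h on leaving out each was -0.004, and counting noise needs it to return in abundant genes, where it was -0.039 over 2470 genes. A batch of the mRNA Light 4 h and Light 8 h libraries alone would leave Dark 0 h like other times, but its ratio deviated 1.465 times as widely as the wider of those. A delay of uncapped transcripts behind mRNA at this step stays open. The mRNA change from Light 8 h to Dark 0 h correlated across genes with the GMUCT change from Dark 0 h to Dark 4 h (r = 0.584), but this value is built from the same correlations of time groups that showed the pattern, so it adds no support. A delay cannot be told apart from mRNA leaves harvested at another moment, or in another state, than the GMUCT leaves, since the labels give no clock times and the 2549 genes with mRNA at Dark 0 h beyond both Light 8 h and Dark 4 h on the same side may arise either way.

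Genes with a rhythm of at least 2-fold differed in GMUCT to mRNA level by -0.064 on the log2 scale from sets of other genes matched on mRNA CPM, which include rhythmic genes of smaller range. The difference was -0.004 with no minimum on the range and -0.0691 ± 0.046 by replicate number (SD, n = 3). The prediction set beforehand took a level outside the range of the matched sets as speaking against mRNA abundance, and used no SD. The level, 0.283, lay below the lowest set, 0.295, but by less than that SD. With no minimum on the range it lay within the sets. For these reasons mRNA abundance cannot be told apart as its cause, although the prediction alone would have set it aside. Neither can transcript length, because 0 identifiers had a length in the reference table.

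Reads in the counters outside genes were not part of the comparisons. Reads overlapping more than 1 gene made up 0.469% of GMUCT counts at Light 8 h and 0.11% at Dark 8 h. Reads placed at several positions reached 40.2% in 1 GMUCT library, replicate 2 of Dark 4 h.

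Regrouped libraries were used to ask whether the counts of genes can come from chance. For any difference among the 6 times and for the 24 h rhythm, 1 of 25 regroupings, the real one, reached the real count in each assay. The counts were 13983 and 13441 genes in mRNA (highest of the others 252 and 2208) and 12087 and 12973 in GMUCT (highest of the others 13 and 1). This speaks against a chance assignment of libraries to times, at the smallest share that 25 regroupings allow. Such regrouping cannot tell time from anything else shared by the 3 libraries of a group. In the ratio 1 of 21 regroupings, the real one, reached the real count (10286 and 8601, highest of the others 0 for both). Those regroupings also broke up the change with time of each assay alone. They therefore cannot say whether chance gives as many changes of the ratio itself. A contrast of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In mRNA the real and highest other counts were 4664 and 0 for Dark 4 h and 5039 and 29 for Dark 8 h against Dark 0 h, 9304 and 0 for Light 4 h and 10201 and 0 for Light 8 h against Light 0 h, and 7265 and 1 for Dark 0 h against Light 0 h and 8605 and 0 against Light 8 h. In GMUCT they were, in the same order, 5339 and 2, 8487 and 1, 6331 and 1, 7730 and 0, 9614 and 1, and 1795 and 0.

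For contrasts of the ratio, 21 splits of 12 libraries were drawn. The real split alone reached its count for Dark 4 h against Dark 0 h (4968 genes, highest other 3646). The same held for Dark 0 h against Light 0 h (6181, highest other 4211) and Light 8 h (7609, highest other 5523). As many genes came from 2 splits for Dark 8 h against Dark 0 h (real 4724, highest other 4938). They came from 4 for Light 4 h against Light 0 h (2393, highest other 8104) and from 3 for Light 8 h against Light 0 h (2830, highest other 8437). In every contrast the highest other counts follow a structure of the samples. They came from splits that left the times of 1 assay whole and so carried its change with time. Of the splits drawn, 2 were of this kind for Dark 4 h and 8 for Dark 8 h against Dark 0 h. Splits that mixed the times in both assays gave at most 36 genes for Dark 8 h and 0 for Light 4 h and Light 8 h. Such splits also broke up the change of each assay alone. Neither kind stands for libraries with an unchanged ratio, so chance was not excluded for any of these contrasts by this count.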

How the results depend on the processing

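Of 390 recomputed counts and summary values under alternative settings, 313 stayed close to the value reported, and so did 436 of 456 with a library or a replicate number left out. Close means within 1.5 times for counts of genes. For correlations, the peak difference and the level it means a shift of less than 1 SD between replicates and no change of sign. For named genes 1072 of 1080 recomputed changes kept direction and passed the threshold, 8 kept direction and did not pass, and 0 reversed. Scaling by relative log expression or upper quartile and a stricter filter moved no count by more than 1.5 times, and limma-voom called 9562 genes with a ratio that changed with time. The fits without Dark 0 h and all alternatives for Dark 0 h against Light 8 h were chosen after seeing the data. Tests of gene lists and a level matched on transcript length had been planned and were not run, since no identifier matched the reference table. At the depth and spread of these libraries, 20 of 100 simulated genes with a log2 change of 1 were recovered in the ratio. In each assay alone 47 were. Only 400 genes changed in each simulation, all with a mean above 1 CPM, so these shares may not hold for the data. Depth itself was not varied.

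The replicate number as a block moved no count by more than 1.5 times, with 13671 genes differing among the times in mRNA, 12049 in GMUCT and 10010 in the ratio. On average the numbers showed little pairing of times within an assay. Deviations of same-numbered libraries correlated at -0.014 in mRNA and 0.033 in GMUCT, against 0.007 and -0.017 for other numbers. Of the libraries, 7 of 18 and 10 of 18 correlated best with their own number, so some pairing is not excluded. These values do not compare mRNA with GMUCT libraries of the same time and number. The ratio was fitted without such pairing.

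Stricter thresholds lowered counts by construction, as fewer genes can pass. An adjusted p of 0.01 left, as higher and lower genes, 1242 and 1191 in mRNA for Dark 4 h and 1382 and 1316 for Dark 8 h against Dark 0 h, and 2184 higher for Dark 0 h against Light 0 h. In GMUCT it left 1658 and 2061 for Light 4 h against Light 0 h, 1385 and 1375 for Dark 4 h and 2731 and 2807 for Dark 8 h against Dark 0 h, and 381 and 328 for Dark 0 h against Light 8 h. In the ratio it left 5636 genes with a 24 h rhythm, 624 and 385 for Light 4 h and 703 and 571 for Light 8 h against Light 0 h, 1259 and 1580 for Dark 4 h and 1106 and 1363 for Dark 8 h against Dark 0 h, 2203 and 1656 for Dark 0 h against Light 0 h, and 2404 lower for Dark 0 h against Light 8 h.

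A 2-fold minimum left, in mRNA, 2695 and 2749 for Light 4 h and 3385 and 2974 for Light 8 h against Light 0 h, 1111 and 1064 for Dark 4 h and 1003 and 1220 for Dark 8 h against Dark 0 h, 1855 and 1842 for Dark 0 h against Light 0 h, and 2126 higher for Dark 0 h against Light 8 h. In GMUCT it left 7462 genes that differed among the times and 7620 with a 24 h rhythm, 1534 and 1058 for Light 4 h and 2039 and 1547 for Light 8 h against Light 0 h, 710 and 1235 for Dark 4 h and 1614 and 2260 for Dark 8 h against Dark 0 h, 2819 and 2055 for Dark 0 h against Light 0 h, and 553 and 394 for Dark 0 h against Light 8 h. In the ratio it left 906 and 574 for Light 4 h and 960 higher for Light 8 h against Light 0 h, 1311 higher for Dark 4 h and 1293 higher for Dark 8 h against Dark 0 h, 1710 lower for Dark 0 h against Light 0 h, and 2262 lower for Dark 0 h against Light 8 h.

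A fit of only the 2 groups compared has fewer libraries to estimate the spread. It called 1400 genes higher in mRNA at Dark 4 h and 1405 at Dark 8 h than at Dark 0 h. In GMUCT it called 1401 higher and 1440 lower at Dark 4 h and 2759 higher at Dark 8 h, and in the ratio 1470 higher and 1714 lower at Dark 4 h and 1168 and 1181 at Dark 8 h. For the ratio at Light 4 h it called 1519 lower, DESeq2 called 1484 lower, and a fit with no filter on low counts 951 higher. The cause was not tested. DESeq2 called 1508 genes higher in GMUCT at Dark 0 h than at Light 8 h, and the cause was not tested.

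Leaving out single libraries gave 1660 to 2720 genes lower in GMUCT at Dark 4 h than at Dark 0 h, and 432 to 1085 higher and 359 to 1265 lower at Dark 0 h than at Light 8 h. For the ratio it gave 724 to 1466 higher and 610 to 1099 lower at Light 4 h, and 846 to 1605 higher at Light 8 h. Each such fit has 1 library fewer, and why single libraries weighed so much was not tested.

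Without Dark 0 h, 6537 genes had a ratio that changed with time and GMUCT peaked 0.35 h after mRNA. The correlation of log2 changes between the assays over genes of at least 10 CPM was 0.166 for Dark 4 h and 0.477 for Dark 8 h against Dark 0 h, and 0.797 for Light 4 h and 0.781 for Light 8 h against Light 0 h. Over all genes, with a replicate number left out, the correlation was -0.021 to 0.055 for Dark 4 h, 0.237 to 0.294 for Dark 8 h, 0.614 to 0.638 for Light 4 h and -0.013 to 0.099 for Dark 0 h against Light 8 h, so the sign of the correlation over all genes was not settled at Dark 4 h and for Dark 0 h against Light 8 h. No replicate was left out at the minimum of 10 CPM. Rhythmic genes differed from matched genes by -0.004 in level with no minimum on the range. The cause was not tested.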

Other observations

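The tests of neighbours were chosen before their results were seen, and the other counts here after.

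More genes had a turning point at Dark 0 h in mRNA than in GMUCT. In mRNA 2549 genes differed at Dark 0 h from both Light 8 h and Dark 4 h in the same direction, 1238 of them above both and 1311 below both, where GMUCT had 503 such genes. Among those in mRNA was gene:Solyc08g080670.1, at 71.4 ± 26.8 CPM (SD, n = 3) at Dark 0 h and at 1.09 ± 0.248 or lower at each other time. Such genes were not counted at other times, so neither number is shown to be unusual. The GMUCT number cannot exceed the 1795 genes that changed from Light 8 h to Dark 0 h, a count that depended on single libraries. The last 4 h of the night were the quietest step in mRNA, with 715 genes higher and 452 lower at Light 0 h than at Dark 8 h, and in the ratio, with 91 and 78. In GMUCT the quietest step was Dark 4 h to Dark 8 h, with 375 higher and 492 lower. Of the 508 genes with mRNA highest at Dark 8 h, 43.7% had their highest GMUCT signal at Light 0 h and 30.9% at Dark 8 h.

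A hypothesis is that genes next to each other in identifier order, which in this naming may follow the chromosome, share the time of their mRNA peak. Among rhythmic genes the median difference in peak time was 4.111 h for 4126 pairs of direct neighbours, below the 5.646 to 6.39 h of 1000 random pairings. Shared reads or recent copies that touch direct neighbours alone do not account for all of it, since genes 3 to 5 identifiers apart differed by 5.533 h over 10814 pairs, also below random pairings (5.799 to 6.268 h). At 20 to 22 apart the median was 5.875 h, within the random range (5.794 to 6.248 h). Runs of gene copies that span several identifiers could also reach pairs 3 to 5 apart. How much of the effect comes from gene copies, at either distance, was not tested.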
